A study of Mus musculus with 10 samples.

How the data were processed

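Total RNA was extracted with RNeasy kits from cells that had been stained for surface markers and nucleic acid dyes, and libraries were made by standard Illumina protocols, per the labels' protocols. The surface markers and gates are not named in the labels. TopHat2 2.0.8b, Cuffdiff 2.1.1 and the mouse genome build mm10 are named in the submitters' processing notes, without their roles or options. The deposited values are read here as FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library), a unit inferred from the named tools and from the values, since no label names it. FPKM are relative within a library, so a difference in total RNA per cell cannot be seen. Which gene annotation and which read strand setting the authors used is not given in the sources used here.

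Each file held 23179 gene rows. Of these, 201 repeated another row exactly, and of 158 symbols on more than 1 row the row with the highest mean was kept, which left 22923 symbols. There were 156 rows that named several genes. Values were used as deposited, on the log2(FPKM + 1) scale, which understates changes of low genes. Depth per library is not known. For genes under 0.5 FPKM in every library, the most common ratio to the value in control cycling thymocytes was taken as the relative weight of 1 fragment. It was 1.03 to 1.33 in the other lymphoid libraries and 2.13 and 2.36 in the granulocyte libraries. Only 25 to 193 genes, of 1056 to 1868 used, lay at that ratio. That 1 fragment weighs more in granulocytes, so that their low values are coarser, is an inference from it. An exact 0 can be a failed estimate, since abundant genes such as S100a9 in granulocytes are listed at 0. Such genes are described as listed at 0, with no ratio.

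Each population and genotype was represented by 1 library from 2 pooled mice. Control and CKO-labelled libraries were therefore compared within a population without a test. A gene was considered with at least 5 FPKM in the higher library and was said to differ at a log2 ratio of at least 1 in either direction. For gene lists the median over members with at least 1 FPKM in the higher library was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of these libraries.

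Tests across libraries used limma 3.58.1 (limma-trend, R 4.3.3), on genes with at least 1 FPKM in 2 or more of the fitted libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The CKO-labelled libraries were compared with control over 4 and over 5 populations with population as a block (3 and 4 residual degrees of freedom). Quiescent and cycling cells were compared in the 8 lymphoid libraries with a block for each lineage and genotype and a state effect per lineage (2 residual degrees of freedom). The difference of that effect between lineages was a contrast of the same fit, and its difference between genotypes was a further term (1 residual degree of freedom). The populations of a genotype come from 1 pool, so these p-values do not measure the spread between animals. The 31 gene lists, with 738 entries of which 732 were found, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists.

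The named genes followed a rule fixed at the same time as the tests. Per population these were the 8 genes with the highest and the 8 with the lowest ratio. Per test they were the 10 called genes with the largest rise and the 10 with the largest fall that changed the same way in every pair. Per list they were the 3 members with the highest mean and the member with the largest change, of which the text gives some. Results for some of these genes are not reported. Dyrk1a, Ccnd3, Ccnd2, Cdkn1b, E2f1 and Mki67 were always included. Predicted genes, receptor and immunoglobulin segments, Xist, Y-linked genes and small RNA genes were skipped in ranking.

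Each fit was tested on simulated data with 200 changed genes. These were drawn from the more abundant genes, with independent noise and the same size of change in every pair. Changes that differ between populations were not simulated. At 2-fold, 98% of changed genes were recovered in the comparison over 4 populations, 96% over 5 populations, 92% for quiescence in thymocytes, 84% in pre-B cells, 63% for the difference between lineages and 98% for the difference between genotypes. The numbers of unchanged genes called were 9, 10, 14, 18, 26 and 98 in that order, so the last fit, with 1 residual degree of freedom, made many false calls on simulated data. Alternatives tried were pseudocounts of 0.1 and 5, other filters, rescaling by median ratios, other blocks and leaving out each pair of libraries. Gene positions are from GENCODE vM21 on the same build. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.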

Results

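RNA sequencing was carried out on 5 cell populations sorted from C57bl/6 mice at 4 weeks of age. In the bone marrow these were large pre-B cells, which divide, small pre-B cells, the stage at which cells leave the cell cycle and rearrange their light chain genes, and mature granulocytes. In the thymus they were cycling and quiescent CD4+CD8+ thymocytes. Each population was taken from a pool of 2 control mice, carrying a floxed Dyrk1a gene without the Mx1-Cre transgene, and from a pool of 2 mice with Mx1-Cre whose genotype is labelled as Dyrk1a-deleted (CKO). DYRK1A is a protein kinase known to phosphorylate D-type cyclins and the LIN52 subunit of the DREAM complex, a repressor of cell-cycle genes. The 10 libraries therefore held 1 library per population and genotype, with 1 pool of mice per genotype and no replication between animals. Sequencing depth was not given. The deposited values summed to between 360394 and 431868 FPKM in the 8 lymphoid libraries and to 830006 and 1074260 FPKM in the control and CKO-labelled granulocytes. Between 9818 and 10350 gene symbols reached 1 FPKM per library. In each population the comparison asks which transcripts differ between the CKO-labelled and the control library. Across populations it asks whether cell-cycle transcripts are lower in quiescent than in cycling cells to the same extent in both pools.

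Dyrk1a itself (chromosome 16, 94570010 to 94695517, plus strand, mm10) was measured first, since it checks the labels. Its gene-level value was not lower in any library labelled CKO. It was 31.2 FPKM in control and 42.3 FPKM in CKO-labelled cycling thymocytes, 37.4 and 44.7 FPKM in quiescent thymocytes, and 32.1 and 41.9 FPKM in granulocytes. Large pre-B cells held 33.2 and 34.4 FPKM, and small pre-B cells 34.1 and 36.9 FPKM. Across the 5 populations the difference was 0.24 on the log2 scale (SE 0.07, limma adjusted p = 0.23). The labels do not say which part of the gene was deleted, and reads from outside that part count toward the value, so it neither bears out nor contradicts the genotype. The libraries are called by their labels throughout. The direction of every difference below rests on those labels.

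**Figure D1:**
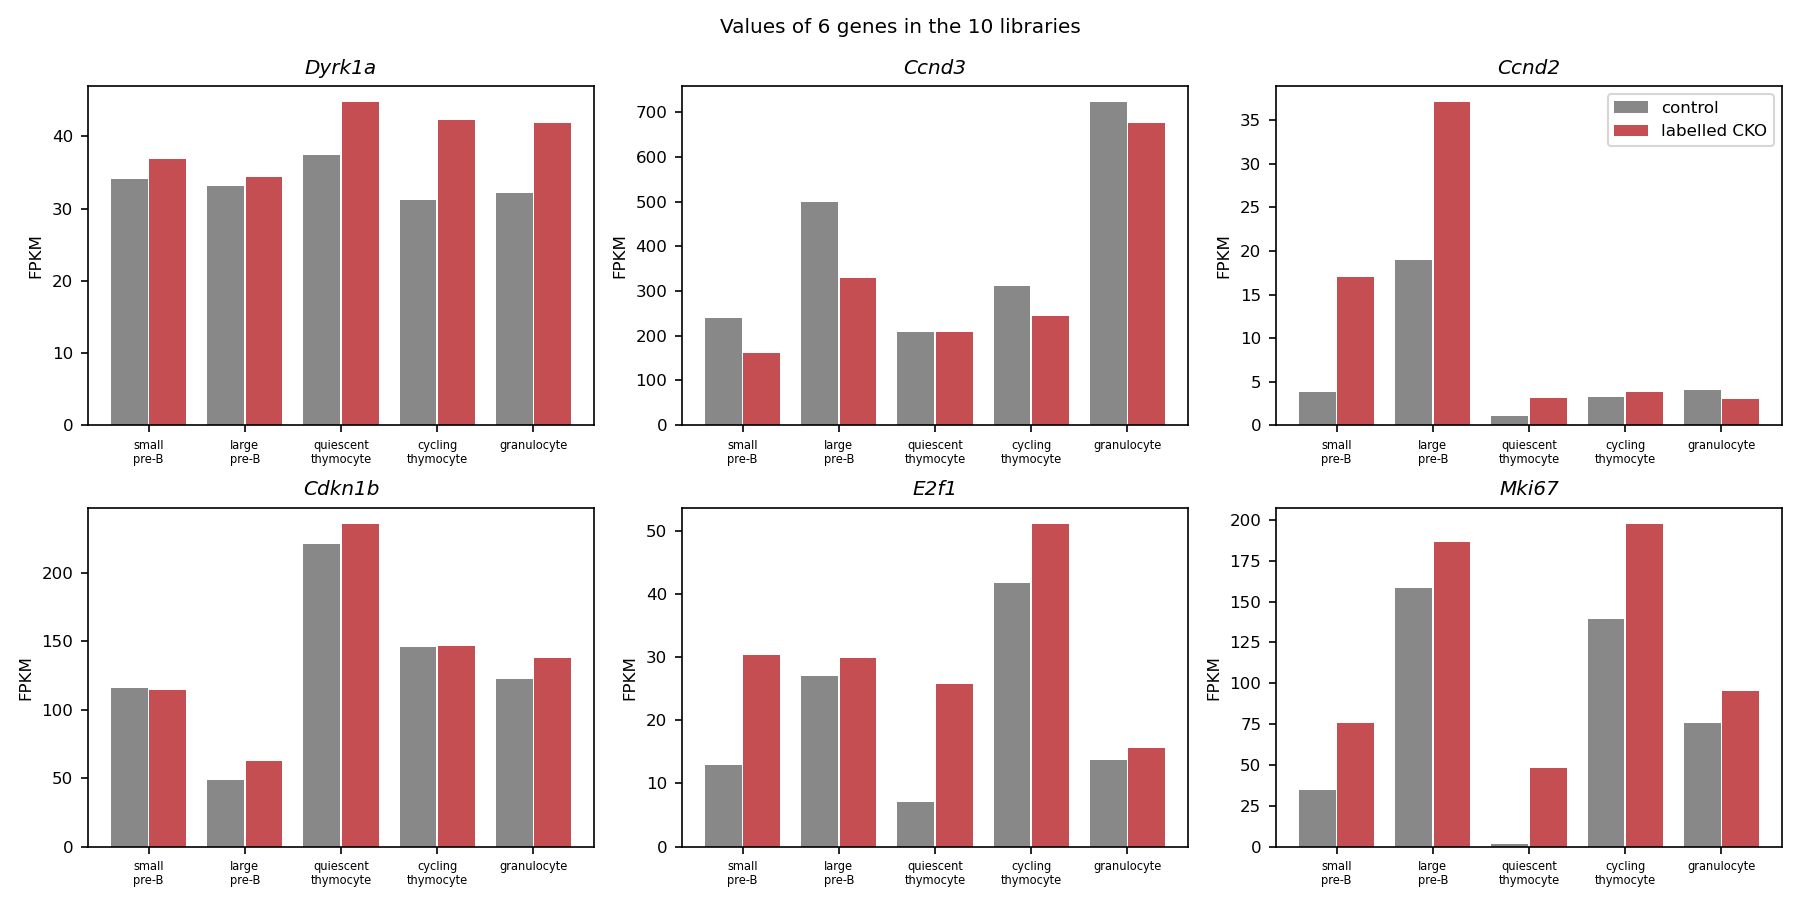
FPKM of 6 genes (vertical axes, linear from 0) in the 5 sorted populations (horizontal axes), with 1 bar per library, grey for control and red for the library labelled CKO. Dyrk1a was no lower in the CKO-labelled libraries, while Mki67 stood at 48.3 against 1.70 FPKM in quiescent thymocytes.

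Quiescent CD4+CD8+ thymocytes labelled CKO held far more transcript of cell-cycle genes than control cells. Mki67, the proliferation marker, stood at 1.70 FPKM in control and 48.3 FPKM in the CKO-labelled library, a log2 ratio of 4.19 on the scale of FPKM plus 1. Cdc6 and Clspn, which act in replication licensing and the replication checkpoint, stood at 0.548 and 22.2 FPKM and at 0.165 and 15.5 FPKM. The mitotic genes Ccna2 (log2 ratio 3.83), Birc5 (3.70) and Ncapg2 (3.82) and the E2F family gene E2f8 (3.96) differed by as much. E2f1 was at 7.13 and 25.7 FPKM. All 39 genes of the fixed list of G2-M mitotic genes were higher, 36 of them at least 2-fold, with a median log2 ratio of 2.29. Of 45 G1-S genes, 43 were higher and 36 at least 2-fold, with a median of 1.66. The 1 member at least 2-fold lower was Gins2, listed at 0 in the CKO-labelled library. Among the higher genes was Pcna, the sliding clamp of the replication fork (242 and 613 FPKM). Both medians lay above those of all 10000 random lists matched on expression. Of 28 DNA repair and checkpoint genes, 13 were at least 2-fold higher (median 0.77). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was also higher (9.82 and 64.1 FPKM), as was Bbc3, which encodes the pro-apoptotic PUMA (63.5 and 197 FPKM). Immediate early and stress genes were higher in 23 of 24 cases (median 0.57), including Nr4a1, a gene induced by T cell receptor signals (309 and 975 FPKM). Genes of the CD4+CD8+ stage were slightly lower (median −0.32, 3 of 29 higher), although Rag1 was at 645 and 599 FPKM. Among single genes the lowest ratios were those of Nav2 (−2.69), the zinc transporter Slc30a4 (−2.67), Smoc1 (−2.60), Sqrdl (−2.51), the laminin chain Lamc1 (−2.24) and B3gnt8 (−2.18). Gse1 and Nolc1 are listed at 0 in the CKO-labelled library and Ankrd10 in the control library, although most other libraries held them, so no ratio is given for them.

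By the rule of size, 287 genes were at least 2-fold higher and 126 at least 2-fold lower in the CKO-labelled quiescent thymocytes, of 7852 genes with at least 5 FPKM in either library. The comparison rests on 1 library per group and has no replicate check. With a pseudocount of 5 the counts were 185 and 56, since low genes then give smaller ratios.

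Cycling CD4+CD8+ thymocytes differed much less, with 29 genes higher and 45 lower of 7755. Of these, 12 were listed at 0 in 1 library and at 10 FPKM or more in the other, and without them 24 were higher and 38 lower. G2-M genes had a median log2 ratio of 0.00 and G1-S genes of 0.20, and no member of either list reached 2-fold. Ccnd3, the cyclin D3 gene, was at 312 FPKM in control and 245 FPKM in the CKO-labelled library. Higher values were found for the peptide transporter gene Slc15a2 (2.78), Lars2 (2.41), Gadd45g (2.12), Olig3 (2.08), Snhg9 (2.03), Bbc3 (1.99) and Tsc22d1 (1.74), all as log2 ratios. Slc30a4 was again lower (−2.80), followed by Dhrs3 (−1.88), Fam43a (−1.80), the inhibitory receptor gene Ctla4 (−1.65) and Ldhb, a lactate dehydrogenase subunit (−1.65, 120 and 37.7 FPKM). All 24 immediate early and stress genes were higher (median 0.53), with Btg2 at 299.5 and 704 FPKM. All 36 cytosolic ribosomal protein genes were lower (median −0.32), as were all 31 genes of oxidative phosphorylation (median −0.20). Cholesterol and lipid synthesis genes were lower in 20 of 24 cases (median −0.42). With 5 FPKM in the pseudocount, 17 genes were higher and 20 lower. Ankrd10, Nrd1 and Osbpl9 are listed at 0 in the CKO-labelled library and Nolc1 in the control library.

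**Figure D2:**
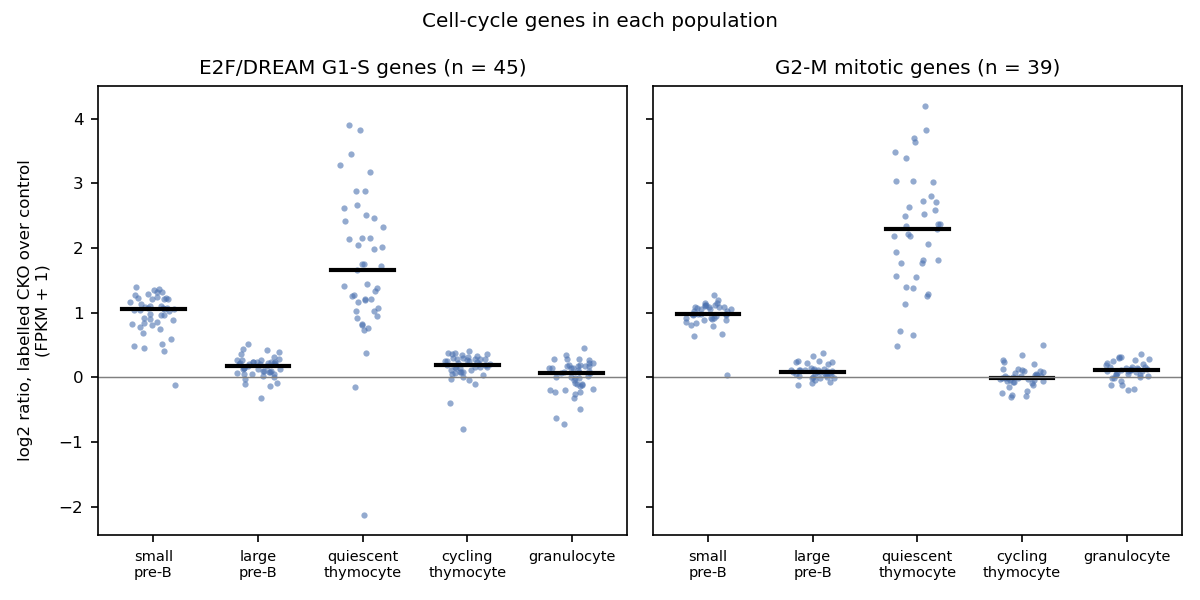
Log2 ratio of FPKM plus 1, library labelled CKO over control (vertical axis), for each gene of the G1-S list (left, n = 45) and the G2-M list (right, n = 39) in the 5 populations (horizontal axis). Each point is 1 gene and black bars are medians, which were 1.66 and 2.29 in quiescent thymocytes and 0.20 and 0.00 in cycling thymocytes.

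Small pre-B cells showed both a difference in cell-cycle genes and one in genes of innate cells. Of 45 G1-S genes, 44 were higher and 26 at least 2-fold (median 1.06), including Rrm2, a ribonucleotide reductase subunit (87.0 and 202 FPKM), and Cdc45 (13.8 and 37.8 FPKM). All 39 G2-M genes were higher, 18 at least 2-fold (median 0.98), including Top2a (62.3 and 144 FPKM). Both medians exceeded those of all 10000 matched random lists. The control library was not free of proliferation transcripts, with Mki67 at 35.0 FPKM. Mki67 was at 158 FPKM in control large pre-B cells and at 1.70 FPKM in control quiescent thymocytes. Cyclin D genes differed in direction. Ccnd1 was at 1.17 and 20.4 FPKM and Ccnd2 at 3.75 and 17.0 FPKM, whereas Ccnd3, the most abundant of them, was at 239.9 and 162 FPKM. Genes of natural killer, innate and mature T cells were at least 2-fold higher in 16 of 18 cases (median 1.84), with granzyme A (Gzma) at 2.03 and 23.3 FPKM, the Fc receptor chain gene Fcer1g at 4.71 and 35.2 FPKM and the chemokine gene Ccl5 at 2.08 and 20.5 FPKM. The highest single ratios belonged to Mpeg1 (3.90), the transcription factor gene Runx2 (3.82), Siglech, a receptor of plasmacytoid dendritic cells (3.71), Ptms (3.53), Cd7 (3.47), Gimap4 (3.40) and Cd300c (3.12). Monocyte and macrophage genes (median 0.77, 5 of 8 higher) and hematopoietic progenitor genes (median 0.88, 7 of 10 higher) were also higher, while secondary granule genes of granulocytes were lower (median −0.39, 3 of 20 higher). Interferon-stimulated genes were higher in 30 of 33 cases (median 0.56), with Bst2 at 21.1 and 134 FPKM.

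In the same pair of libraries, genes of the pre-B stage and of its later steps were lower. The pre-B cell list had a median of −0.62 (5 of 28 higher). The B cell receptor components Cd79a (1238 and 675 FPKM) and Cd79b (1264 and 727 FPKM) were among its most abundant members. Small pre-B differentiation genes had a median of −0.54, with Cd2 at 101 and 22.7 FPKM and the transcription factor gene Spib at 839 and 420 FPKM. Plasma and mature B cell genes had a median of −0.80. Of 18 genes of the pre-B cell receptor and interleukin-7 program of large pre-B cells, 11 were higher and 8 at least 2-fold (median 0.57), among them the surrogate light chain genes Igll1 (107 and 440 FPKM) and Vpreb1 (132 and 418 FPKM). Dntt, the terminal transferase gene and 1 of the 5 higher members of the pre-B cell list, was at 68.4 and 326 FPKM. Among quiescence genes, Klf2 was at 283 and 116 FPKM and Cdkn1b, which encodes p27, at 116 and 114 FPKM. The lowest single ratios were those of Reln (−3.24), the collagen gene Col5a3 (−3.16), Hmgcll1 (−3.02), Mgst1 (−2.82), the calcium channel subunit gene Cacna2d1 (−2.72), Lrrn3 (−2.69) and Rgs16 (−2.31). In all, 371 genes were at least 2-fold higher and 146 lower, of 8207. With a pseudocount of 5 these were 134 and 75, and Ankrd10 is listed at 0 in the CKO-labelled library.

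Large pre-B cells, the dividing counterpart, had 69 genes higher and 77 lower of 7920. G1-S genes had a median log2 ratio of 0.18 and G2-M genes of 0.08, with no member at 2-fold. Ccnd3 was at 500.2 and 330 FPKM and Ccnd2 at 18.9 and 37.1 FPKM, and Igll1 at 282 and 462 FPKM. The small pre-B differentiation list had a median of −0.53 (4 of 20 higher), with the interleukin-2 receptor gene Il2ra at 14.2 and 3.53 FPKM. Granzyme genes were higher (Gzma 9.95 and 41.6 FPKM, Gzmb 0.888 and 6.57 FPKM), as were Gimap4 (log2 ratio 2.57), Emp1 (2.03), Egfl7 (1.93) and the interferon-induced GTPase genes Tgtp1 (2.20) and Tgtp2 (1.82), a near-identical pair whose reads can be shared. The lowest ratios were those of Hmgcll1 (−2.56), Ddc (−2.30), Mgst1 (−2.15), Tubb2b (−2.10), Col5a3 (−2.07), Glcci1 (−1.98), Pfn2 (−1.92) and Steap4 (−1.86). Markers of other bone marrow cells also differed. Primary granule genes of granulocytes had a median of −0.98, with myeloperoxidase (Mpo) at 365 and 159 FPKM, monocyte and macrophage genes of −0.81 and erythroid genes of −0.55, while the natural killer and innate list had a median of 0.84. Among the most abundant members of that list Gzma was higher, but Fcer1g was lower (39.85 and 24.64 FPKM) and Nkg7 nearly unchanged (25.98 and 27.54 FPKM). With a pseudocount of 5 there were 33 genes in each direction, and Nolc1 is listed at 0 in the control library.

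**Figure D3:**
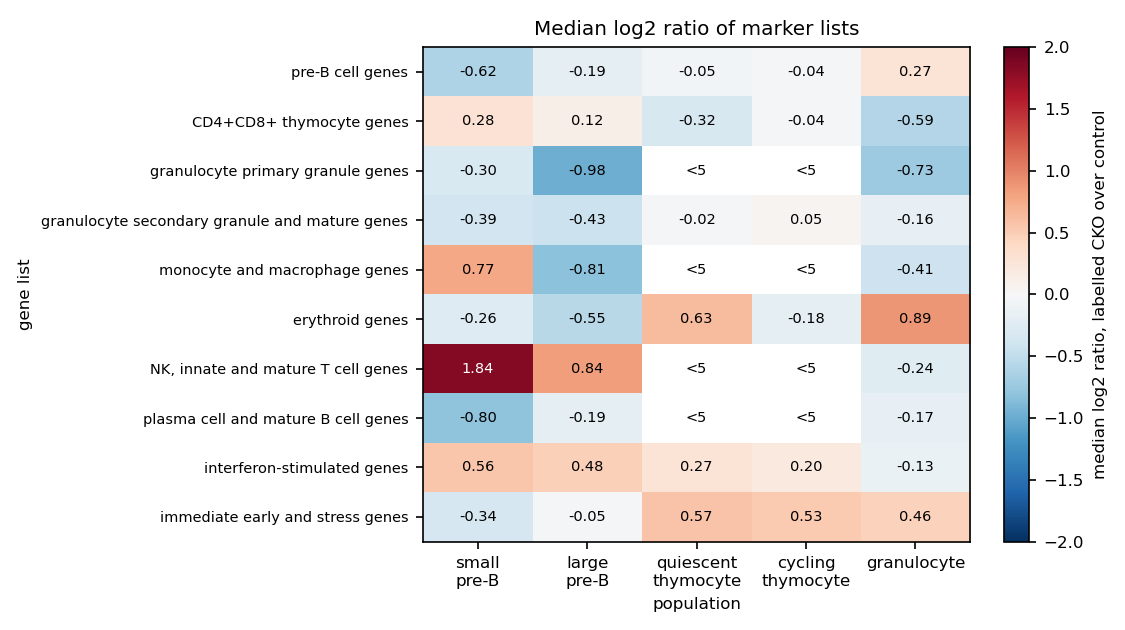
Median log2 ratio of FPKM plus 1, library labelled CKO over control, for 10 fixed gene lists (rows) in the 5 populations (columns), with red for higher and blue for lower and the value printed in each cell. Cells marked <5 had fewer than 5 members at 1 FPKM or more. Natural killer and innate genes stood at 1.84 in small and 0.84 in large pre-B cells.

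Across genes, the log2 ratios of the populations were related to different extents. Pearson's r was 0.62 between small and large pre-B cells, 0.46 between small pre-B cells and quiescent thymocytes, 0.46 between the thymocyte populations and 0.41 between cycling thymocytes and granulocytes. The other 6 of the 10 values lay between 0.06 and 0.26, over 6395 to 7535 genes. Genes are not independent replicates, and all 5 comparisons come from the same pair of pools. Small pre-B cells and quiescent thymocytes shared 124 genes at least 2-fold higher in both, where independent lists would share 8.32, and 6 at least 2-fold lower in both, where they would share 0.579. Small and large pre-B cells shared 43 higher and 29 lower genes (2.20 and 0.586 for independent lists), and the thymocyte populations 14 and 27 (0.785 and 0.327). The other 7 pairs of populations shared 4 to 9 higher and 2 to 9 lower genes. Independent lists would share 0.048 to 1.05 and 0.060 to 0.428, so these pairs also shared more. Y-linked genes, which were higher in every CKO-labelled library, were not left out of these counts.

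The libraries of mature granulocytes had 45 genes higher and 139 lower of 7884. Both held transcripts of proliferating cells, with Mki67 at 76.0 and 95.1 FPKM and Top2a at 121.5 and 127 FPKM. Cell-cycle genes differed little between them, with medians of 0.07 for G1-S and 0.11 for G2-M genes and no member at 2-fold. Primary granule genes, which are made at an early step of granulocyte maturation, had a median of −0.73, with proteinase 3 (Prtn3) at 325 and 109 FPKM. Erythroid genes were higher (median 0.89, 12 of 13 higher), with the alpha globin genes Hba-a1 and Hba-a2, reported on 1 row, at 51.2 and 192 FPKM. Monocyte and macrophage genes had a median of −0.41. Single genes with high ratios were Pfas, an enzyme gene of purine synthesis (4.10 and 934 FPKM), the MHC class I genes H2-Q6 (2.74) and H2-Q7 (2.25), which share reads with close relatives, H1f0 (2.38) and the chemokine gene Cxcl2 (2.27). Low ratios were found for Dok2 (−3.22), Tcf7 (−3.10), Cldn1 (−2.85), Ednra (−2.73), Serpinb10-ps (−2.62), Cdc42ep2 (−2.34), Ces1d (−2.09) and Lmo1 (−2.08). S100a8 is listed at 0 in the control library and at 246142 FPKM in the CKO-labelled library, and S100a9 at 0 in both, although they are among the most abundant granulocyte transcripts. Ngp is also listed at 0 in the control library. With a pseudocount of 5, 26 genes were higher and 62 lower.

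To ask which genes differed alike in every population, the libraries labelled CKO were compared with their controls over the 4 lymphoid populations with population as a block. Few genes passed, 3 higher and 1 lower, while 1867 of 11126 had an unadjusted p under 0.05. Tsc22d1, a transcription factor gene, rose by 1.87 on the log2 scale (SE 0.14, limma adjusted p = 0.038, higher in 4 of 4 pairs). Lmo4, which encodes a LIM-only transcriptional cofactor, fell by 0.93 (SE 0.06, limma adjusted p = 0.027, lower in 4 of 4 pairs). The other 2 of the 4 called genes were the Y-linked Ddx3y and Eif2s3y. With the granulocytes included, 6 genes were called and 1970 of 11715 had an unadjusted p under 0.05: the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and 2 lower genes. Of these, Hibadh, an enzyme gene of valine breakdown, fell by 0.69 (SE 0.06, limma adjusted p = 0.024) and was lower in 5 of 5 pairs. No lower gene was called in this fit without either thymocyte pair, without the large pre-B pair or without the population block, and Hibadh was not called in the lymphoid fit. Ccnd2 had a log2 difference of 1.02 (limma adjusted p = 0.23), Ccnd3 of −0.38 (limma adjusted p = 0.25), E2f1 of 0.83 (limma adjusted p = 0.25) and Mki67 of 1.51 (limma adjusted p = 0.31) in the lymphoid fit, none past the threshold.

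Lists were called where single genes were not in this fit. G1-S genes had a median of 0.71 and were called by camera with a preset correlation of 0.01 (adjusted p = 1.98e-14), although none of the 45 members passed over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.57. G2-M genes (median 0.90), DNA repair genes (0.42) and interferon-stimulated genes (0.33) were likewise called with the preset correlation, at adjusted p values of 1.18e-10, 8.40e-05 and 1.01e-08, and not with the estimated one (adjusted p = 0.57 each). Of 18 p53 target genes none passed over all genes and 7 rose adjusted over the list alone. A p from this fit measures how alike the 2 pools differ over populations, not the spread between animals. Without the large or the small pre-B pair no gene was called in the lymphoid fit, and without either thymocyte pair 1 gene was, while without the population block 2 genes were, both higher.

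The change from cycling to quiescent thymocytes, compared within each pool, was broad. Of 11126 genes tested, 2804 rose and 2193 fell in quiescent cells (limma, adjusted over all genes). All 39 G2-M genes fell (median −3.40), led by the survivin gene Birc5, which fell by 4.67 (SE 0.84, limma adjusted p = 0.011), while Ccna2 (−4.63), Cdca3 (−4.48) and Ube2c (−4.40) fell nearly as far. Of 45 G1-S genes 43 fell and 1 rose (median −1.83). Gins2, a replicative helicase subunit gene among the named genes, is listed at 0 in the CKO-labelled quiescent library, so its change is not given. Of 28 DNA repair genes 22 fell and 2 rose, and of 31 oxidative phosphorylation genes 24 fell (median −0.58). Genes of the CD4+CD8+ stage rose in 12 of 29 cases and fell in 1, with a rise of 1.13 for Rag1 (SE 0.23, limma adjusted p = 0.014). Cdkn1b rose by 0.64 (SE 0.12, limma adjusted p = 0.013) and Pik3ip1, an inhibitor of phosphatidylinositol 3-kinase, by 1.83, while E2f1 fell by 1.68. The largest rises were those of Fam65a (2.93), Slc6a19 (2.76), Tcp11l2 (2.68), Tle2 (2.66), Gramd3 (2.42), Spo11 (2.41) and the chemokine receptor gene Ccr9 (2.30). The list calls of camera held with the preset correlation for 11 lists and for none with an estimated one (adjusted p = 0.87 for the G2-M list). Only 2 pools stand behind each gene. Without the control pool's thymocyte pair 3 genes rose and 1 fell, and without the CKO-labelled pair 1633 rose and 1581 fell.

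Small pre-B cells differed from large pre-B cells as widely, with 2847 genes higher and 2430 lower (limma, adjusted over all genes). Genes of B cell maturation rose: 21 of 28 pre-B cell genes and 15 of 21 small pre-B differentiation genes. Ms4a1, which encodes CD20, rose by 3.47 (SE 0.30, limma adjusted p = 0.0027), Rag1 by 2.60 and Cd40 by 2.92. The pro-apoptotic gene Bmf rose by 3.07, the anti-proliferative gene Btg1 by 2.24 and Cdkn1b by 1.04. Other large rises were those of Col5a3 (3.35), Faim3 (3.33), Pde4c (3.15), Cacna1e (3.05) and Tmem163 (3.05). Growth genes fell. Of 30 genes of ribosome biogenesis and MYC targets 25 fell (median −1.23), with Npm1 falling by 1.47 and Srm by 2.63. Of 36 ribosomal protein genes 31 fell, of 31 oxidative phosphorylation genes 28 and of 21 glycolysis genes 14, among them Ldha, which fell by 1.86. Ccnd3 fell by 1.04 (SE 0.12, limma adjusted p = 0.0042) and Ccnd2 by 1.57. Of 39 G2-M genes 31 fell (median −2.21) and of 45 G1-S genes 17 did (median −1.11). The pools differed in the G1-S genes, of which 40 were at least 2-fold lower in control small pre-B cells and 5 in CKO-labelled ones. The deepest falls were those of Igj (−6.25), the primary granule genes Mpo (−5.23), Prtn3 (−4.95), Ctsg (−4.86) and Elane (−4.81), and the mitotic gene Ube2c (−3.48). Of the primary granule list 12 of 14 genes fell, and of the erythroid list 15 of 17. Mpo was at 365 FPKM in the control large pre-B library. The 19 list calls made with the preset correlation were lost with an estimated one (adjusted p = 0.58 for the G2-M and primary granule lists and 0.33 for ribosome biogenesis). Without the control pool's pre-B pair no gene rose and 3 fell, and without the CKO-labelled pair 845 rose and 581 fell.

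**Figure D4:**
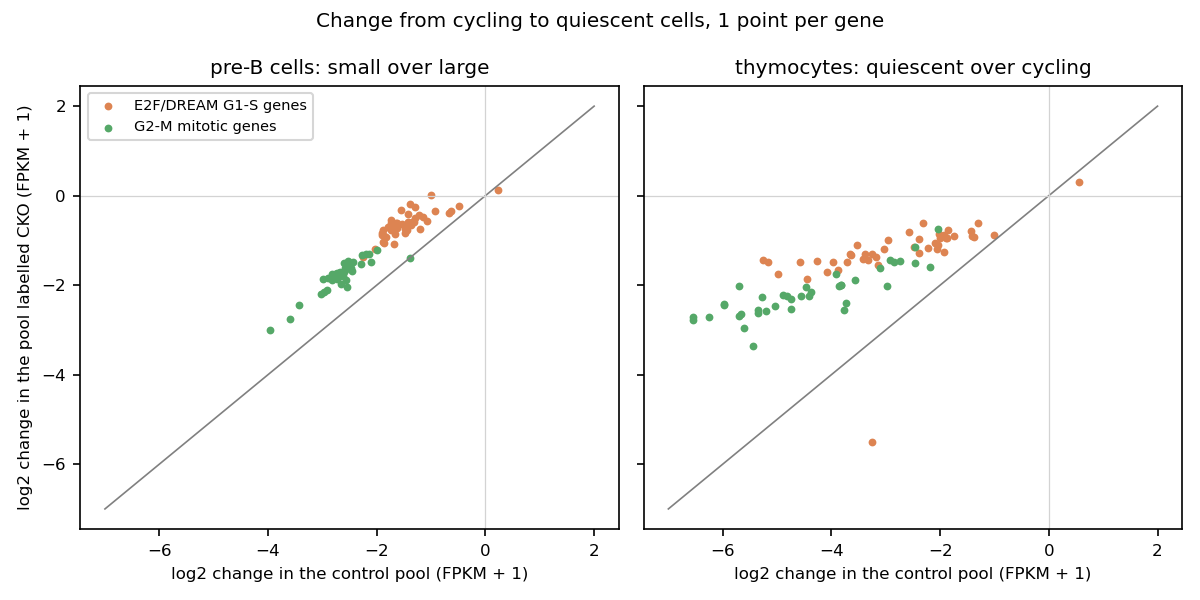
Log2 change of FPKM plus 1 from cycling to quiescent cells in the control pool (horizontal axis) and in the pool labelled CKO (vertical axis), for pre-B cells (left) and thymocytes (right), with 1 point per gene of the G1-S and G2-M lists and a grey line of equal change. The median change of G1-S genes in thymocytes was −2.57 in the control pool and −1.18 in the CKO-labelled pool.

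Whether quiescence changed the same genes in both lineages was tested as the difference of the 2 changes. The difference, pre-B cells minus thymocytes, was above 0 for 358 genes and below 0 for 403, 761 in all (limma, adjusted over all genes). It was above 0 for 10 of 21 small pre-B differentiation genes, with Ms4a1 at 3.60 (SE 0.43, limma adjusted p = 0.023), Spib at 2.97 and Cd40 at 2.97. For Ms4a1 and Cd40 it came almost wholly from pre-B cells, whose change alone was 3.47 and 2.92. The difference was below 0 for 12 of 30 genes of ribosome biogenesis and MYC targets and 7 of 21 glycolysis genes, with Ldha at −1.46 (SE 0.14, limma adjusted p = 0.017) and Pdk1 at −2.05. Leaving out the control or the CKO-labelled pre-B pair left no called gene.

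The fall of cell-cycle transcripts from cycling to quiescent cells was smaller in the pool labelled CKO in both lineages. The cycling libraries differed little in these genes, so this mostly restates the difference between the quiescent libraries. Bulk values cannot tell a smaller fall per cell from a larger share of sorted cells in part of the cycle. In control thymocytes the median G2-M gene was lower in quiescent cells by −4.56 on the log2 scale and in the CKO-labelled pool by −2.25. In pre-B cells these medians were −2.61 and −1.73. For G1-S genes they were −2.57 and −1.18 in thymocytes and −1.54 and −0.65 in pre-B cells. The test of this difference, with the lineages as replicates and 1 residual degree of freedom, called 5 genes over all genes tested and 1358 at an unadjusted p under 0.05 (limma). The 5 were the small RNA genes Mir3096, Snora31, Snora34, Snora7a and Snord22, named after their values were seen. Each is listed at 0 in at least 2 of the 8 libraries fitted, and such a 0 can be a failed estimate. No gene of the G1-S or G2-M lists passed over all genes, whereas 41 of 45 and 38 of 39 did, all with a smaller fall, adjusted over the list alone. Members of a list are not independent, and both lineages come from the same 2 pools, so these counts are not separate findings. On simulated data this fit called 98 unchanged genes. E2f1 had a difference of 1.23 (SE 0.15, limma adjusted p = 0.15) and Mki67 of 2.27 (SE 0.63, limma adjusted p = 0.27). Camera called both lists with the preset correlation (adjusted p = 2.12e-34 and 1.18e-33) and neither with an estimated one (adjusted p = 0.87). Cholesterol and lipid synthesis genes differed in the same direction in 9 of 24 cases adjusted over the list alone, with Idi1 at 0.99 (SE 0.16, limma adjusted p = 0.15).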

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

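The tests of differences between lineages and pools were fixed beforehand, and the tests of explanations and the splits of the libraries were chosen after the result was seen. The quiescence change differed between lineages for 761 genes. The difference, pre-B cells minus thymocytes, was above 0 for the B cell genes Ms4a1 (3.60 on the log2 scale), Spib (2.97) and Cd40 (2.97), and for Faim3 (3.51), Col5a3 (3.35), Pde4c (3.16), Tmem163 (2.99), Gh (2.95) and Neurl3 (2.90). It was below 0 for Igj (−6.04) and for the primary granule genes Mpo (−5.27), Prtn3 (−4.90), Ctsg (−4.86) and Elane (−4.76). The primary granule genes are markers of another cell type that thymocytes nearly lacked (Mpo at most 0.145 FPKM). Also below 0 were F13a1 (−3.51), Ms4a3 (−3.34), Fam83d (−3.24), Car1 (−3.22) and Aqp1 (−3.07). In pre-B cells alone Ms4a3 and Car1 changed by −3.34 and −3.22. From large to small pre-B cells the erythroid list had medians of −2.15 in the control and −1.63 in the CKO-labelled pool, and the monocyte list −1.33 and 0.47. Which of these genes came from other sorted cells was not tested. For several genes above 0 the difference came almost wholly from pre-B cells. Their change alone was 3.47 for Ms4a1, 3.33 for Faim3, 3.35 for Col5a3, 3.15 for Pde4c, 3.05 for Tmem163 and 2.96 for Gh. The quiescence change differed between the CKO-labelled and control pools for 5 genes, all of them small RNA genes listed at 0 in at least 2 of the 8 libraries fitted, where a 0 can be a failed estimate.

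The Y-linked genes were higher in every CKO-labelled library, with log2 differences over 5 populations of 4.27 for Eif2s3y, 3.54 for Ddx3y, 1.90 for Kdm5d and 1.62 for Uty. All 5 CKO-labelled libraries held all 4 genes above 1 FPKM and all 5 control libraries held them under 0.1 FPKM, so the pools differed in sex. Xist was at 23.3 to 65.3 FPKM in the control libraries, as from female mice, and at 8.09 to 45.6 FPKM in the CKO-labelled libraries, as from a pool of male and female mice. Sex and genotype therefore cannot be told apart in any comparison of the pools.

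The higher cell-cycle genes in quiescent CKO-labelled thymocytes and small pre-B cells were weighed against 3 explanations. If a share of cells with the whole profile of the cycling library were mixed in, G1-S and G2-M genes would imply the same share. They implied 33.9% and 17.5% in thymocytes and 45.7% and 17.6% in pre-B cells, ratios of 1.94 (95% bootstrap interval over genes 1.75 to 2.36) and 2.60 (2.25 to 2.90), which argues against that mixture alone. Other genes higher in cycling cells implied 23.1% (quartiles 13.3% to 32.5%, 784 genes) in thymocytes and 25.7% (15.8% to 39.0%, 812 genes) in pre-B cells. The test covers only cells with the whole cycling profile. It does not weigh a share of cells from part of the cycle, with G1-S but few G2-M transcripts. A scaling factor would move all genes of a library alike, but the median log2 ratio of G1-S genes lay 1.67 (1.26 to 2.05) and 1.16 (1.06 to 1.20) above that of all genes, which argues against scaling. With 1 pool of mice per genotype, another difference between the pools could not be tested.

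The calls across populations were compared with other splits of the libraries. Of 32 splits of the 8 lymphoid libraries 5 called at least the 4 genes of the real split, the highest other 190, and of 100 splits of all 10 libraries 11 called at least 6, the highest other 42. Swapping labels within populations gave as many calls in 1 of 8 splits, the real one, with 1 gene at most in the others, and in 1 of 16 with 0 genes in the others. These swaps are too few for a share under 0.05.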

How the results depend on the processing

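The counts of called genes and lists were repeated with other settings, and the cause of a move was not tested. The overlaps between populations and the counts adjusted over a list alone were not repeated, nor was a pair left out of the difference between the CKO-labelled and control pools. Leaving out genes listed at 0, marker genes of other cell types, and pairs in the difference between lineages were added after the data were seen. The 2-fold counts in the small and the large pre-B, the quiescent and the cycling thymocyte and the granulocyte comparison, 517, 146, 413, 74 and 184 in the main setting, were 209, 66, 241, 37 and 88 with a pseudocount of 5. They were 224, 58, 173, 33 and 90 with at least 20 FPKM in the higher library and 1313, 429, 1092, 289 and 516 with a 1.5-fold rule, and 115 in cycling thymocytes with at least 1 FPKM. With genes listed at 0 left out they were 513, 135, 402, 62 and 178. Without the marker genes of other cell types that are on the lists used here, small pre-B cells gave 481. Genes of those cells that are on no list were still counted. The 4 genes called over lymphoid populations became 0 with no filter, where 2093 had an unadjusted p under 0.05, 10 with a pseudocount of 0.1, 2 without the population block and 0 to 1 with a pair left out. The 6 called over 5 populations became 1 with no filter and 1 to 4 with a pair left out. The 4997 genes of thymocyte quiescence ranged from 4 to 3795 with a pair left out, and were 3214 without the CKO-labelled thymocyte pair. The 5277 of the pre-B comparison ranged from 3 to 4972, with 1426 without the CKO-labelled pre-B pair. Without the block that pairs the libraries of a pool, 3634 (1981 higher, 1653 lower) and 3690 (1980 and 1710) genes were called. The 761 genes that differed between lineages became 0 with no filter, 361 with a pseudocount of 0.1 and 0 to 359 with a pair left out, and the 5 that differed between pools became 0 with no filter. Of the lists called with the preset correlation, 18 and 17 over 4 and 5 populations, 11 in thymocytes, 19 in pre-B cells, 18 between lineages and 11 between pools, 0 were called in each with an estimated correlation. With fry 0 were called over 4 populations, 0 over 5, 2 in thymocytes, 13 in pre-B cells (11 of them among the 19), 4 between lineages and 0 between pools. DESeq2 was not run, because the deposited values are not counts.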

Other observations

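The tests in this part were chosen after the result was seen, except the search for a chromosome segment. Among 52 genes, the Y-linked ones left out, that differed by at least 0.5 on the log2 scale in the same direction in all 4 lymphoid populations, 23 were higher and 29 lower in the CKO-labelled libraries. The higher genes included 3 of the p53 target list, namely the pro-apoptotic Bbc3 (log2 ratios of 1.20, 1.19, 1.62 and 1.99 in the small and then the large pre-B pair and the quiescent and then the cycling thymocyte pair), Pmaip1 (0.90, 0.77, 1.35 and 0.51) and Phlda3 (1.16, 0.54, 1.16 and 0.86). Dyrk3, a kinase gene of the same family as Dyrk1a, was higher as well (1.52, 0.59, 2.06 and 0.71). The lower genes included the histone demethylase gene Kdm5b (−1.05, −0.89, −1.63 and −1.52), Zhx2 (−1.51, −0.94, −1.37 and −0.96) and Il2ra (−1.60, −1.75, −0.74 and −0.51). Each ratio rests on 1 library per group.

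A segment of another strain's chromosome carried along with the Mx1-Cre transgene, which the control mice lacked, would group such genes by position. Of the 52 genes 48 had a position, and 10 pairs lay within 2 Mb of each other, where random sets gave 1 to 9 in 95% of cases. Hspa1a, Hspa1b, Tnf and H2-Q7 on chromosome 17 made up 6 of the pairs. Without Hspa1b, a near copy of its neighbour Hspa1a, 7 pairs remained, at percentile 92.1 of the random sets, so the test does not decide.

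The innate and natural killer genes that were higher in small CKO-labelled pre-B cells were weighed next. A lower share of pre-B cells would raise all other cell types alike, but the natural killer list lay 2.23 above the secondary granule list of granulocytes (95% bootstrap interval over genes 1.79 to 2.71), which argues against all types rising alike, not against more of several, since the monocyte and progenitor lists had medians of 0.77 and 0.88. Among the 3 most abundant members of each of these lists, Mpeg1 was higher and the others were lower or differed little. A hypothesis is that more plasmacytoid dendritic cells were sorted, and of 20 of their markers all 8 under 5 FPKM in the control library, 3 already named ones left out, were at least 2-fold higher (100%), against 13.3% of 2763 other genes as low, including Klk1 (0.602 and 6.49 FPKM), Lag3 (0.390 and 5.49 FPKM) and Ctsl (4.88 and 27.0 FPKM). That list was written after Siglech, Runx2 and Cd300c had been seen, and of the markers already abundant in the control library Irf8 was at 92.5 and 212 FPKM, Grn at 66.2 and 67.1 FPKM, Spib at 839 and 420 FPKM and Ly6d at 939 and 468 FPKM. The test of these markers does not bear on the natural killer genes Gzma and Ccl5. Whether more natural killer cells were sorted was not tested. The labels do not list the surface markers used for sorting, and with 1 pool per genotype a difference between the pools other than the genotype could not be tested.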
